A study of Homo sapiens with 6 samples.

How the data were processed

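Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in human primary CD4+ T cells from 2 donors. The labels describe isolated cells that were stimulated for 24 hours with beads carrying antibodies to CD3 and CD28, in the presence of interleukin-2, before formaldehyde fixation and sonication. One immunoprecipitation used an antibody to p50, the subunit made from NFKB1, and one used an antibody to p65, the subunit encoded by RELA. Input, the sonicated chromatin with no antibody, was sequenced as the background. Each of the 3 groups (Input, p50 and p65) held 2 libraries, 1 per donor, called replicate 1 and replicate 2 here, for 6 libraries in all.

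The deposited table holds whole-number counts for 248697 non-overlapping genomic regions, 1 column per library, without normalization. Per the submitters' processing notes, Bowtie2 2.2.9, SAMtools 1.4 and Picard 1.134 were used with the hg19 build, and the notes as used here assign no role to each tool. How the regions were called, on which libraries, whether duplicate reads were removed and whether reads or fragments were counted are not given in the sources used here. Coordinates are printed as deposited, on hg19. The file does not say whether its starts count from 0 or from 1, so a start may be off by 1 base.

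Only the 22 autosomes were used, which left 247953 regions. The 744 other rows, on the sex chromosomes, the mitochondrial genome and unplaced or alternative sequence, entered no test. Autosomal regions were 111 to 14668 bp wide with a median of 265 bp. The autosomal counts summed to 2960861 and 2458747 in the Input libraries, 3503134 and 2782883 in the p50 libraries, and 6452983 and 8204225 in the p65 libraries. These sums cover only reads inside the deposited regions and are not sequencing depths. A region had a median of 9 to 11 counts in the Input and p50 libraries and 23 to 29 in the p65 libraries.

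Regions were kept for testing by the filterByExpr rule of edgeR (minimum count of 10, applied by group), which left 191156 regions. Counts were scaled by TMM factors on the library sums, and a quasi-likelihood model (edgeR 4.0.16, glmQLFit and glmQLFTest, robust, limma 3.58.1, R 4.3.3) with a mean for each group was fitted to all 6 libraries, which left 3 residual degrees of freedom. Altogether 3 two-sided comparisons were made, p50 against Input, p65 against Input, and p65 against p50, each with Benjamini-Hochberg adjustment over the tested regions and a threshold of 0.05. A region called higher than Input is named enriched below. Normalised counts (CPM) are counts divided by the TMM-scaled library sum over the tested regions and brought to a common sum of 1e6, and the mean and SD of a group are over its 2 libraries. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Binomial intervals are exact (Clopper-Pearson) at 95%, Poisson intervals of a count ratio or of a density are exact, and all of these cover counting error only, because reads without molecular identifiers are not independent molecules. Where both libraries of a group had no count, a fold change was computed against a floor of 3 counts per library.

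The same donors supplied all 3 groups, so the replicate numbers pair the libraries by donor. Deviations from the group means of libraries from the same donor correlated at 0.014 (Input with p50), 0.0247 (Input with p65) and 0.0425 (p50 with p65) across regions. The model without the donor was the primary one, and the model with a donor block was an alternative. Counts of the 2 libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.05 for Input, 1.23 for p50 and 1.81 for p65.

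The test was run first on simulated counts for the 191156 regions with known changes. For p50 against Input it recovered 84% of 100 regions raised 4-fold, 8% of those raised 2-fold and 11% of those lowered 4-fold, with 7 false calls. For p65 against Input the values were 95%, 4% and 48%, with 5 false calls. For p65 against p50 they were 97%, 11% and 45%, with 9 false calls. Enrichments of 2-fold and most depletions were therefore below the reach of these counts.

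Named regions were chosen by a rule fixed before the data were examined. For each comparison and direction it takes the 12 regions with the largest fold change among those past the threshold, with the same sign in both donors and a mean log CPM above the median of the tested regions. Regions named outside the rule are said to be so. The alternatives were library sums without TMM, DESeq2 1.42.0, abundance-trended offsets, no count filter, a filter of 20 counts in 2 libraries, the donor block with and without trended offsets, a fit of only the 2 groups compared, and each library left out in turn. Fits added after the data were seen are said to be so. The overlap of the p50 and p65 comparisons, which share the Input libraries, was set beside 5 simulated draws in which neither immunoprecipitation differed from Input. Because such draws held at most 2 calls at the threshold, lists of the observed sizes were taken from them by smallest p. Figures were drawn with matplotlib 3.10.9.

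Planned tests of gene lists, of promoter share and of the κB motif were not run. They need an annotation and a sequence of hg19, and the gene table at hand is of another build (GRCh38.p14). No gene name is therefore attached to any region.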

Results

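The 6 libraries profiled p50 and p65, subunits of the transcription factor NF-κB, in CD4+ T cells 24 hours after stimulation through CD3 and CD28. p50 lacks a transactivation domain and p65 carries one, and the pair forms the classical NF-κB dimer. The comparisons asked where on the genome each subunit gave more counts than Input chromatin, and where the profiles of the subunits differed. Each group held 2 libraries from 2 donors, and 191156 autosomal regions had enough counts to be tested.

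p50 was enriched over Input at 4786 regions, 2.5% of those tested. The median enrichment was 4.12-fold (log2 fold change 2.04), 2510 regions passed 4-fold and 175 passed 16-fold. Both donors showed the increase at 4782 of the 4786 regions. With 2 libraries per group, a call nearly requires such agreement, here and in the comparisons below, so it is not separate support. Enriched regions were wider than the tested regions, with a median of 414 bp against 306 bp. The median enriched region had 41.8 ± 6.68 CPM per kb in the p50 libraries (normalised counts, mean of the library medians ± SD, n = 2) and 9.93 ± 0.0303 in Input.

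Among the named regions, the p50-enriched region with the smallest p lay on chromosome 13, at 24848537 to 24849279. It carried 327.4 ± 50.9 CPM in p50 and 7.59 ± 0.445 in Input (SD, n = 2), a 42.8-fold difference (log2 fold change 5.42 ± 0.275 SE, edgeR adjusted p = 3.37e-81). A region on chromosome 20 at 46115667 to 46116400 reached 309.8 ± 39.9 CPM against 8.13 ± 1.37, a 38.3-fold difference. On chromosome 19, the region from 51944747 to 51945577 had 233.4 ± 18.5 CPM in p50 and 5.70 ± 0.988 in Input. Chromosome 2 held 3 further regions of this strength, at 68989659 to 68990337 (42.2-fold), 64431184 to 64431857 (41.5-fold) and 208393998 to 208394482 (38.3-fold). The region on chromosome 3 from 187464568 to 187465211 was 38.7-fold higher in p50. On chromosome 1, the regions from 24814530 to 24815172 and from 143743181 to 143743817 were 47.4-fold and 60-fold higher.

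Of the 12 named regions, 3 had almost no Input counts, which leaves their ratios imprecise. On chromosome 2 at 112153071 to 112153390, both Input libraries had 0 counts and p50 had 53 and 56, so p50 was at least 16.9-fold higher, with a floor of 3 counts per library. The region on chromosome 1 from 144519802 to 144520252 had 1 count in each Input library against 157 and 125 in p50, a ratio of 131 with a counting interval of 35.9 to 1090. On chromosome 11, 67675502 to 67675921 had 3 counts in each Input library, and its ratio was 52.3 (23.8 to 144). All 12 regions stayed past the threshold under each alternative in which they were tested.

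**Figure D1:**
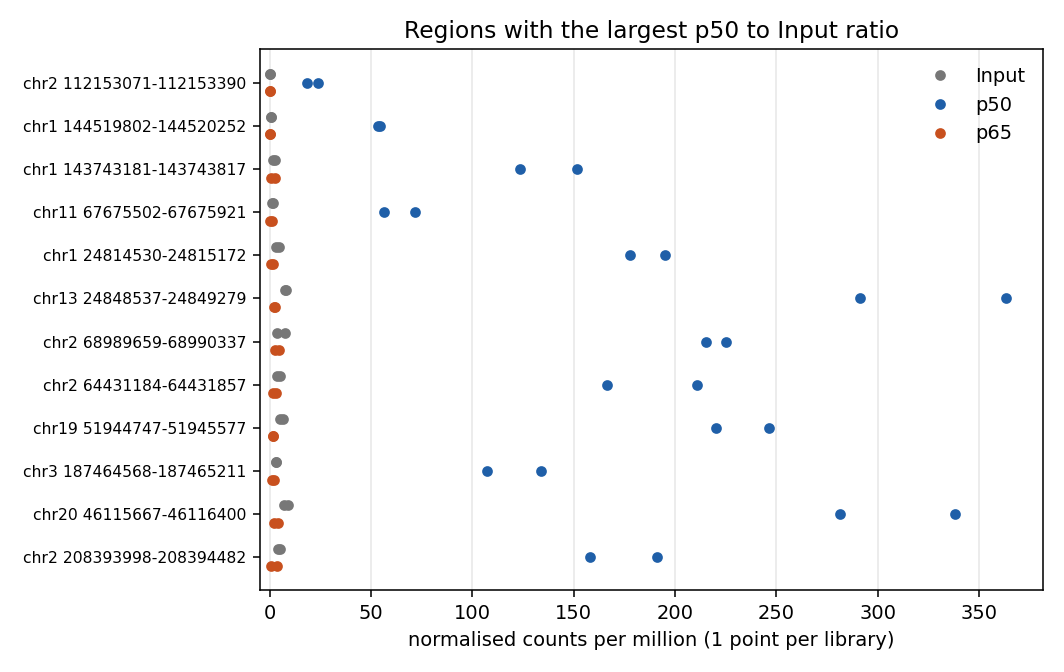
Normalised counts (CPM, horizontal axis) of the 12 named p50-enriched regions (rows, hg19 coordinates as deposited), with 1 point per library for Input, p50 and p65. In every row both p50 libraries lie above all Input and p65 libraries, and the region on chromosome 13 from 24848537 to 24849279 has a p50 mean of 327.4.

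DESeq2 called 2822 of the 4786 regions and no other p50-enriched region. Leaving out p50 replicate 1 gave 2630, whereas leaving out any other library gave 3311 to 5427.

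Per length of chromosome spanned by tested regions, p50 enrichment was densest on chromosome 19, with 31.4 enriched regions per 10 Mb (Poisson interval 27.0 to 36.3), on chromosome 17 with 29.6 (25.9 to 33.6) and on chromosome 22 with 24.6 (19.7 to 30.4). Chromosomes 13, 4, 9 and 18 were the sparsest, with 10.9, 11.4, 11.6 and 11.7. The regions offered for testing were spread in a different order. Chromosomes 4 and 13 held 1160 tested regions per 10 Mb each, whereas chromosome 19 held 180 and chromosome 22 held 137. As a result, 17.4% of the tested regions on chromosome 19 and 18.0% of those on chromosome 22 were p50-enriched, against 0.981% on chromosome 4 and 0.937% on chromosome 13.

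**Figure D2:**
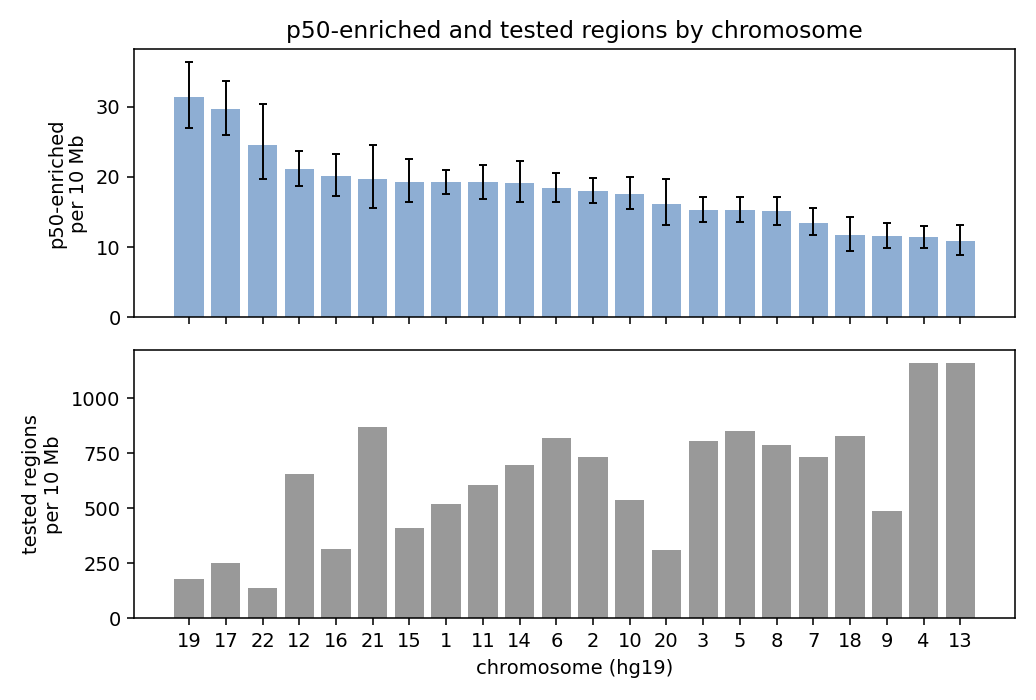
Number of p50-enriched regions per 10 Mb of each autosome (upper panel, bars with 95% Poisson intervals) and of all tested regions per 10 Mb (lower panel), with chromosomes ordered by the upper panel. Chromosome 19 has the most p50-enriched regions per 10 Mb (31.4) and only 180 tested regions per 10 Mb.

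Counts below Input in the p50 libraries were rare, at 93 regions with a median log2 fold change of −1.64. The largest drop among the named ones, on chromosome 10 at 84525461 to 84525763, had 2.15 ± 0.575 CPM in p50 and 7.63 ± 0.143 in Input (SD, n = 2; 3.58-fold lower, edgeR adjusted p = 0.00807). Similar ratios were found on chromosome 2 at 58203567 to 58203972 (3.57-fold lower) and on chromosome 3 at 110327954 to 110328306 (3.53-fold lower). DESeq2 called 0 such regions, though it set no adjusted p for 88946 of the tested regions. In edgeR 4353 passed an unadjusted p of 0.05, fewer than evenly spread p-values would give in this direction with no effect. The p-values were thus not evenly spread, and this number does not tell whether the 93 calls are chance. The number of depleted regions was 214 without TMM and 152 with the 2 groups alone. It was 61 with the p65 libraries left out of the filter and the fit, a fit added after the data were seen. Most of the 93 regions were no longer called when either Input library or either p50 library was left out. Most stayed called without either p65 library.

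With counts scaled over the deposited regions themselves, few regions stood out above Input in p65. A p65 gain shared by most of these regions would be scaled away, so the number of calls does not measure it. Only 13 regions were higher in p65, with a median of 3.26-fold (log2 fold change 1.71), in both donors at all 13. The best-covered of the named ones were on chromosome 12 at 83784433 to 83785174, with 10.15 ± 0.698 CPM in p65 and 4.61 ± 1.2 in Input (SD, n = 2; 2.22-fold, edgeR adjusted p = 0.0374), and on chromosome 4 at 63781414 to 63782390, with 10.46 ± 3.04 against 4.83 ± 1.69 (2.14-fold, adjusted p = 0.0457). The region on chromosome 4 was the closest of the 13 to the threshold. The donor block kept 11 of the 13 calls, as did trended offsets and the fit with no count filter. The largest ratio among the regions taken by the naming rule was 3.26-fold, on chromosome 6 at 68793558 to 68793859 (adjusted p = 0.0186). An unadjusted p of 0.05 was passed by 2474 regions, fewer than evenly spread p-values would give in this direction with no effect. This shortfall shows uneven p-values and does not tell whether the 13 calls are chance. DESeq2 set no adjusted p for 122301 of the tested regions in this comparison, among them the region on chromosome 6. DESeq2 called 0 regions, the fit of the 2 groups alone called 4, and leaving out Input replicate 2, p65 replicate 1 or p65 replicate 2 gave 8, 61 or 3.

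In the opposite direction, p65 lay below Input at 2623 regions, 1.37% of those tested, with a median log2 fold change of −1.99 (3.98-fold lower). Both donors showed this at 2621 of them, and 1289 were at least 4-fold lower. The named regions had few p65 counts. On chromosome 17 at 74268008 to 74268554, p65 had 0.633 ± 0.516 CPM and Input 7.11 ± 1.53 (SD, n = 2; edgeR adjusted p = 9.08e-09), a p65 to Input ratio of 0.0848 with a counting interval of 0.0339 to 0.187. The region on chromosome 1 from 156066776 to 156067220 had a ratio of 0.0854 (0.0363 to 0.180), and that on chromosome 19 from 48018324 to 48018839 had 0.0772 (0.0331 to 0.161).

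The planned scalings kept this split, with 17 regions higher and 2348 lower on library sums and 15 and 2658 with trended offsets. All of them rest on counts in the deposited regions, so they could not reveal p65 counts inflated in most regions by the choice of regions. With TMM factors taken from the p50-enriched regions alone, a choice made after the data were seen that by construction moves every region up by the p65 deficit of those regions, 153927 regions were higher and 387 lower in p65, so that 99.7% of the calls were higher instead of 0.493%, and the median log2 fold change of all regions moved from −0.02 to 1.29. DESeq2 called 609 lower regions, the filter of 20 counts 1283, the 2 groups alone 971, and leaving out Input replicate 1, Input replicate 2, p50 replicate 1 or p65 replicate 2 gave 680, 878, 1678 or 979.

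The regions where p65 lay below Input were largely p50-enriched. Of the 4786 p50-enriched regions, 1628 (34.0%) were also below Input in p65, which was 62.1% of all regions with p65 below Input. Independent lists of these sizes would share 65.7 regions, and lists of the same sizes, taken by smallest p from 5 simulated draws with no effect and the same shared Input, shared 0 to 1. In those draws the p50 and p65 fold changes correlated at 0.594, which by itself makes opposite calls rare. Neither reference allows for a choice of regions on p65 counts, so the excess does not exclude such a choice. With 1 Input library given to each comparison, a fit added after the data were seen, 412 or 510 regions were shared, against 12.8 or 15.2 for independent lists. An example is the region on chromosome 1 at 9747242 to 9747722, with 37.1 ± 10.4 CPM in p50, 6.98 ± 3.44 in Input and 0.335 ± 0.474 in p65 (SD, n = 2). Another, on chromosome 14 at 81685947 to 81686460, had 28.5 ± 0.538, 6.16 ± 0.345 and 0.467 ± 0.281. The shared count and its alternatives were added after the data were seen. It was 422 with DESeq2 and 553 with the 2 groups alone. It was 299, 435, 787 or 561 without Input replicate 1, Input replicate 2, p50 replicate 1 or p65 replicate 2.

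In the median p50-enriched region, p65 had 4.0 ± 0.463 CPM per kb (mean of the library medians ± SD, n = 2), against 9.93 ± 0.0303 in Input. In the 185275 regions called in neither comparison with Input, the medians of the groups were close, at 14.5 ± 0.00394 for p65, 14.3 ± 0.0347 for Input and 13.9 ± 0.160 for p50. The scaling and the lack of a call in these regions bring the medians together. Their closeness therefore does not measure the p65 background against Input. From the 1197 regions with the weakest p50 enrichment to the 1197 with the strongest, the p50 median rose from 31.7 ± 6.51 to 84.4 ± 14.9, while p65 went from 4.73 ± 0.434 to 3.32 ± 0.559 and Input from 11.5 ± 0.0748 to 8.75 ± 0.0723.

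**Figure D3:**
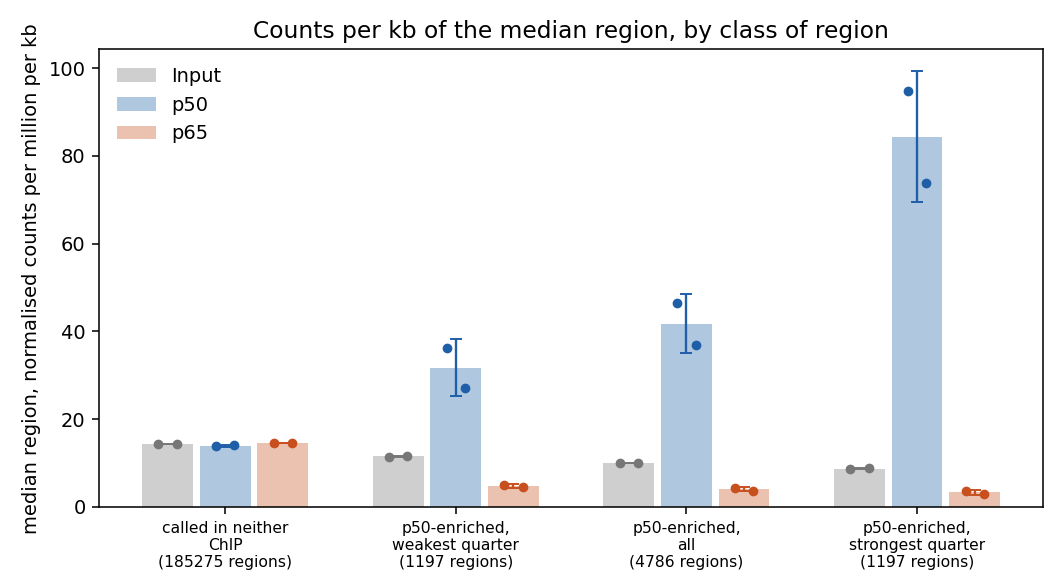
Normalised counts of the median region (CPM per kb, vertical axis) in regions called in neither comparison with Input, in all p50-enriched regions and in the 1197 weakest and 1197 strongest of them, for Input, p50 and p65. Bars are means of the library medians, error bars SD and points the medians of the 2 libraries of each group. The groups lie near 14 in uncalled regions, where the scaling and the lack of a call bring them together. In p50-enriched regions p50 reaches 41.8 while p65 is at 4.0.

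In strongly p50-enriched regions, the p65 to Input ratio was low and varied little with p50 strength. Its median log2 value was −1.17 where the p50 log2 fold change was 1.5 to 2 (2022 regions), −1.31 at 2 to 3, −1.34 at 3 to 4 and −1.44 above 4 (177 regions). Where the p50 log2 fold change was 1 to 1.5 (4563 regions), the p65 median was 0.149 with an interquartile range of −1.32 to 0.777. Below a p50 log2 fold change of 1, the p65 ratio rose with the p50 ratio, from −0.41 to 0.38. The shared Input libraries give such a rise without any effect. Over all tested regions, the log2 fold changes of p50 and p65 had a covariance of 0.00381, against 0.129 in the simulation, a difference of −0.125. Their correlation across regions, which are not independent replicates, was 0.0128 against a simulated 0.594.

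**Figure D4:**
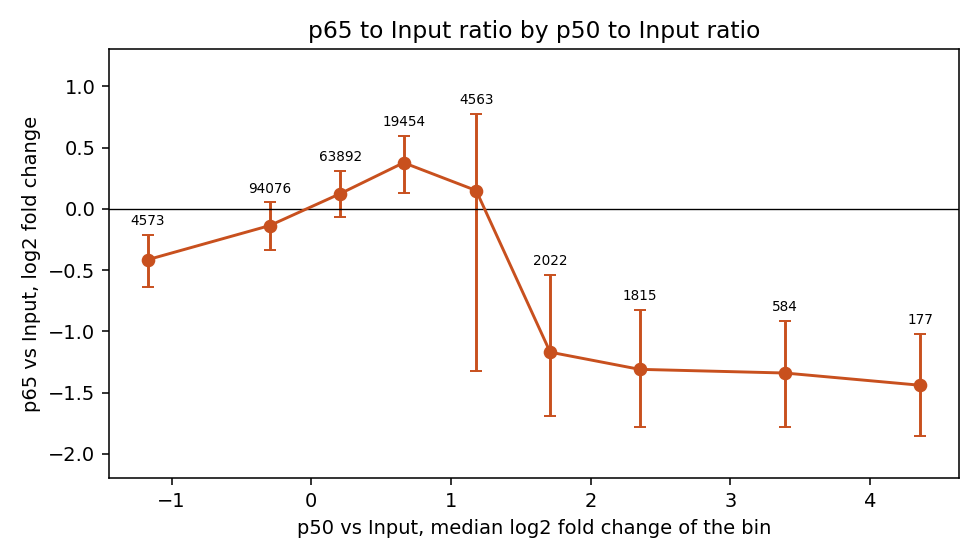
Median p65 vs Input log2 fold change (points, with the interquartile range as bars and the number of regions above) in bins of the p50 vs Input log2 fold change (horizontal axis, bin median). The p65 median lies at −1.17 to −1.44 in the 4 bins with the strongest p50 enrichment.

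Regions enriched in both immunoprecipitations numbered 3, against 0.325 for independent lists. Lists of the same sizes from the 5 simulated draws shared 9 to 13 through the shared Input alone. Neither value gives the chance level for the observed lists. Independent lists leave out the shared Input, and the draws hold no p50 enrichment. Whether the 3 are an excess was therefore not decided. They lay on chromosome 12 at 83784433 to 83785174 (p50 log2 fold change 1.42, p65 1.15), on chromosome 10 at 19685865 to 19686374 (1.49 and 1.47) and, named after its values were seen, on chromosome 10 at 57841881 to 57842134 (counts of 5 and 0 in Input, 11 and 13 in p50, 19 and 42 in p65). The overlap was 1 without TMM, 0 with DESeq2 and 0 at an adjusted p of 0.01. With 1 Input library given to each comparison it was 0 in both ways of splitting them.

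Compared directly, p65 was lower than p50 at 8301 regions, 4.34% of those tested, with a median of 7.88-fold (log2 fold change −2.98). Of these, 7023 were at least 4-fold and 1607 at least 16-fold lower, and 8289 were lower in both donors. They included 4717 (98.6%) of the 4786 p50-enriched regions. On chromosome 17 at 36857189 to 36858261, p50 had 258.2 ± 1.2 CPM, p65 1.502 ± 0.228 and Input 9.52 ± 0.686 (SD, n = 2), and p65 was 170-fold lower than p50 (edgeR adjusted p = 1.7e-127). Chromosome 8 held 4 of the 12 named regions, among them 101514581 to 101515521, where p50 had 331.8 ± 87.9 CPM and p65 2.57 ± 2.49 (135-fold), and 29426998 to 29427833, with 198.4 ± 10.5 against 1.60 ± 0.558 (124-fold). The filter of 20 counts gave 5102 regions. These counts and ratios rest on the same p65 scaling as the comparison with Input. If the choice of regions inflated the p65 counts in most regions, the drop of p65 below p50 would be overstated.

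p65 exceeded p50 at 71 regions, with a median of 2.82-fold. At the region of chromosome 9 from 106722144 to 106722633, p65 had 6.76 ± 0.0794 CPM, close to the 6.91 ± 1.41 of Input, and p50 had 2.18 ± 1.12 (SD, n = 2; 3.17-fold, edgeR adjusted p = 0.00384). On chromosome 3 at 162651650 to 162652073, p65 had 6.26 ± 0.318 and p50 1.93 ± 0.275 (3.23-fold, adjusted p = 0.00645). Only 5 of the 71 reached 4-fold. DESeq2 called 0. In edgeR 3330 regions passed an unadjusted p of 0.05, fewer than evenly spread p-values would give in this direction with no effect. The p-values were thus uneven, and this number does not tell whether the 71 calls are chance. Library sums without TMM gave 391 and moved the median log2 fold change of all regions to 0.20. Most of the 71 regions were no longer called when either p50 library or p65 replicate 2 was left out. Most stayed called without p65 replicate 1 or either Input library.

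Counts were most concentrated in the p50 libraries. The most covered 1% of regions took 10.4% (exact binomial interval 10.37 to 10.43) and 8.92% (8.88 to 8.95) of the counts of the p50 libraries, a mean of 9.66 ± 1.05 (SD, n = 2). The shares were 5.49% and 5.45% in Input (5.47 ± 0.0255) and 4.54% and 4.65% in p65 (4.59 ± 0.0799). Both p50 libraries exceeded both Input libraries and both p65 libraries were below them. The shares were set only beside the spread of the libraries, since the smallest exact permutation p of 2 against 2 libraries is 0.33. Regions were ranked within each library on its own counts. The median region had 23 to 29 counts in the p65 libraries and 9 to 11 in Input. The lower p65 share was not separated from this difference.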

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

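The added fits, and the count of p50-enriched regions with p65 below Input with all of its alternatives, were chosen only after the data had been seen, and the other alternatives were planned. Without any TMM factor, p50-depleted regions numbered 214, p65 exceeded p50 at 391 and the overlap of enriched regions was 1. The median log2 fold change of all regions then lay at −0.147 for p50 against Input and 0.198 for p65 against p50. DESeq2 gave 2822 p50-enriched and 0 p50-depleted regions, 0 p65-enriched regions and 609 with p65 below Input, 0 with p65 above p50, an overlap of 0, and 422 regions p50-enriched with p65 below Input. It set no adjusted p for 88946 regions in the p50 and 122301 in the p65 comparison with Input. With no count filter 60 regions were p50-depleted. The filter of 20 counts left 148428 regions and gave 1283 with p65 below Input and 5102 with p65 below p50. The fit of the 2 groups alone gave 152 p50-depleted regions, 4 p65-enriched, 971 with p65 below Input and 553 p50-enriched with p65 below Input. At an adjusted p of 0.01 the overlap was 0. In the added fits, 61 regions were p50-depleted without the p65 libraries, and TMM factors from the p50-enriched regions gave 153927 p65-enriched regions and 387 below Input, as their construction requires. With 1 Input library for each comparison the overlap was 0 in both splits, and 412 or 510 regions were p50-enriched with p65 below Input. Apart from this shift and the smaller tests of the filters, the causes were not tested.

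With each library left out in turn, a fit in which the remaining library of that group is assumed to vary like the others, the counts ranged from 2630 to 5427 for p50-enriched, 22 to 152 for p50-depleted, 3 to 61 for p65-enriched, 680 to 2786 for p65 below Input, 50 to 298 for p65 above p50, 5768 to 8444 for p65 below p50, and 299 to 1713 for p50-enriched with p65 below Input. The donor block gave 4828 p50-enriched and 108 p50-depleted regions, 13 p65-enriched and 2559 below Input, 82 with p65 above p50 and 8339 below, an overlap of 3, and 1544 p50-enriched regions with p65 below Input, so the pairing moved no count by over 1.5 times. With trended offsets as well, the block gave 19 p65-enriched regions. The most covered 5% of regions took 14.26% of counts in Input, 19.8% in p50 and 13.42% in p65, and among tested regions the most covered 1% took 5.498% in Input.

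Named regions had the same sign in both donors, which leaves little room for reversals. Of 1060 comparisons of a named region with an alternative, 873 kept direction and threshold, 187 lost the threshold and 0 reversed. The 12 named p50-enriched regions lost none, whereas 12 of the 13 p65-enriched regions lost it without p65 replicate 2 and as many without either Input replicate. Few counts per region limit what can be detected, since a 2-fold increase was recovered in 8% of simulated cases for p50 and 4% for p65. Gene list, promoter and motif alternatives were not run.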

Other observations

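All tests in this part were chosen only after the results were seen. The windows of 500 kb richest in p50-enriched regions were read off after their values were known. A window on chromosome 6 held 12 p50-enriched regions among 25 tested, between 143123164 and 143461546, with a median log2 fold change of 2.56. On the same chromosome, 11 of 18 tested regions were enriched between 90675272 and 90984705 and 10 of 24 between 138002014 and 138249280. On chromosome 17, 11 of 13 were enriched between 38020153 and 38480636, on chromosome 3 11 of 15 between 71059868 and 71447761, and on chromosome 2 11 of 17 between 231523934 and 231839321. A window on chromosome 21 had all 8 of its tested regions enriched, between 32503069 and 32833630.

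p50-enriched regions lay close together. Of the 4786, 15.1% had another with its midpoint within 10 kb, against a mean of 9.09% and a maximum of 10.9% in 1000 shuffles of the labels among the tested regions of each chromosome (one-sided permutation p = 0.001, the smallest these shuffles can give), which argues against uneven spacing of the deposited regions as the whole cause. After regions under 2 kb apart were merged into 1 locus, the share was 10.4% against a mean of 4.92% and a maximum of 6.51% (permutation p = 0.001 again). This argues against broad peaks split into pieces under 2 kb apart as the whole cause. Pieces 2 to 10 kb apart were not merged, so broad peaks split that way stay open. The fullest window held 12 enriched regions, and the fullest window of any shuffle held 23. No p was computed for this count, so whether the fullest window exceeds chance was not decided. No biological explanation was tested, and a candidate explanation that stays open is that p50 binds clustered regulatory elements, which needs an hg19 annotation.

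For p65 counts below Input at p50-enriched regions, 1 technical explanation had its predicted trace, namely regions chosen on the p65 libraries' own counts. Within regions of equal width that were not called in either comparison with Input, the counts of the 2 p65 libraries correlated negatively, with a mean Spearman value of −0.214 (bootstrap interval −0.223 to −0.205 over 351 widths and 195027 regions, of which 38575 had failed the count filter), whereas the Input pair gave 0.05 and the p50 pair 0.133, and over tested regions alone the values were −0.242, 0.00896 and 0.106. Such a trade-off may arise if a region was listed when either p65 library was high by chance, and the p65 baseline would then be inflated everywhere except at regions listed for p50. Exchanged p65 and Input labels stay open. Over the 8301 regions with p65 below p50, Input counts per kb did not rise with p50 counts per kb (Spearman −0.147, interval −0.166 to −0.124). An exchange predicted such a rise, but p65 counts per kb did not rise either (−0.00788). Over all tested regions, log2 counts of the Input libraries correlated with those of the p50 libraries at 0.391 to 0.442. Those of the p65 libraries did so at 0.215 to 0.365. The lower p65 values would follow from an exchange. They could also follow from any cause of low p65 counts where p50 is high, which is the pattern itself, so they do not decide the question. Poorer coverage of GC-rich sequence in the p65 libraries stays open as a part, because the median log2 ratio at p50-enriched regions of the GC-rich chromosomes 16, 17, 19, 20 and 22 minus that of the AT-rich chromosomes 3, 4, 5, 6 and 13 was −0.342, against −1.31 for the whole set. No sequence of the regions was used, and a real exclusion of p65 was not tested.

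Few regions rose above Input in the p65 libraries, and weak p65 enrichment hidden by low counts stays open. From the 1197 weakest to the 1197 strongest p50-enriched regions, p65 counts summed over the regions and divided by their summed length changed by a factor of 0.703 and Input by 0.787, a ratio of 0.894 (bootstrap interval 0.856 to 0.934), while p50 changed by 3.36. For the median region, the measure given with the results, the factors were 0.701, 0.761 and 2.66, and the ratio was 0.921. This ratio decides nothing, because a listing of regions on p65 counts could set it, and 63 of the weakest (5.26%) but 0 of the strongest regions had p65 at or above 10.9 CPM per kb, which all but the lowest 5% of uncalled regions reached. A p65 gain shared by most deposited regions would be removed by the scaling and stays open as well. The efficiency of the p65 antibody and a lack of p65 on chromatin at 24 hours were not tested.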
